A study of Mus musculus with 4 samples.

How the data were processed

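The study prepared 4 single-cell RNA libraries from distal colon with a droplet-based kit that counts the 3′ ends of polyadenylated RNA. Per the labels' protocols, the tissue was minced and digested with Liberase, a collagenase blend, and the cells went directly into library preparation. The kit named there is Chromium Next GEM 3′ v3.1 of 10x Genomics. The submitters' processing notes name FastQC, Cell Ranger and the build mm10, and their versions and settings are not given in the sources used here. The annotation release is also not given there.

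For each library 2 deposited files were analysed, as the authors deposited them. The first lists the barcodes that the authors' pipeline kept as cells, each of 16 bases with the same suffix. The second lists the gene ID, symbol and feature type of each gene counted. Neither holds a measured value, so counts per cell, UMI totals, genes per cell, mitochondrial shares and doublets were not analysed here. The only depth given here is therefore the number of cell barcodes per library, 17288 to 20937, and the sequencing depth behind each cell is unknown. Because a called barcode can be a cell, a doublet or a droplet of free RNA, and the calling rule depends on depth, the number of barcodes is not a direct count of cells in the tissue.

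Libraries were grouped by the genotype label, with 2 libraries in each of 2 groups, and sex was taken from the titles. Choices of groups, tests, gene lists and alternatives were made before the data were examined, unless stated otherwise. The comparisons of expression planned with count models were not made, as no counts were analysed. The rule for naming genes was to give Wdhd1 and the members of the fixed lists, and, without expression values, to name them only for whether the lists of counted genes hold them. Cell type markers were fixed in the same way and are reported only as listed or not.

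Numbers of barcodes were compared between genotypes with an exact two-sided permutation test over the libraries. Nothing says how many mice stand behind a library, so the test takes libraries as its units. Differences between libraries may be partly technical. Intervals of 95% for numbers of barcodes are exact Poisson intervals, and those for ratios within a sex come from the exact binomial interval. They cover counting error only. The plan set no error model for the number of barcodes in a library, so the intervals per library and within a sex depart from it. Barcodes shared by a pair of libraries were counted as identical sequences. They were compared with the product of the numbers of barcodes in the pair, divided by the size of the list the barcodes were drawn from. The v3 list was taken to hold 6794880 barcodes, from general knowledge, and the list itself was not used here. Whether every barcode in it can be drawn with this kit was not checked. A further expected number was chosen after seeing the data. It uses the combinations that the barcode parts allow, where bases 1 to 7 form the first part, bases 8 and 9 a link, and bases 10 to 16 the last part. These steps were also run on simulated data, in which a linked pool was built with the part layout and links seen in the real barcodes. For 4 simulated libraries of the observed sizes, the sharing between libraries gave 98.1% of the true size of a linked pool and 107% of the true size of a pool as large as the v3 list. The parts gave 100% of the linked pool, which follows from its being built on that layout and does not test the layout.

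Gene IDs were matched without their version to GENCODE M21, which describes GRCm38, the assembly of mm10. Of the 32285 IDs, 50 had no match. The codon of residue 819 was found by translating each coding transcript and mapping its bases to the genome through the annotated exons. Exon overlap was computed between genes that are both listed, as the percent of a gene's merged exon bases. Symbols that were not found were looked up under their other names in the RefSeq gene table of GRCm38.p6. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9. The alternatives tried were dropping barcodes found in another library, merging barcodes 1 base apart, leaving out each library, comparing within each sex, other sizes of the barcode list and matching genes by symbol.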

Results

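Single-cell RNA libraries were prepared from the distal colon of C57BL/6J mice, an inbred strain, in 4 captures of mixed colon cells. The design set a wild-type genotype against AND-1 T819A, a threonine-to-alanine substitution in AND-1. AND-1 is a replisome protein that links the replicative helicase to DNA polymerase alpha, and in the mouse it is encoded by Wdhd1. Per the labels, mice carried tumours induced by azoxymethane, an alkylating colon carcinogen. They also received hydroxyurea, an inhibitor of ribonucleotide reductase that slows replication forks. The tissue taken was normal colon beside the tumours, at 38 weeks. Each genotype had 2 libraries, 1 labelled female and 1 labelled male, although the series description speaks of female mice only. The comparison asks how the cells of the distal colon differ between the genotypes in mice given these treatments. The data analysed here were the lists of barcodes called as cells and the lists of genes counted. Expression values per cell were not analysed here, so no gene is given a level or a change, and cell types were not assigned.

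The residue altered in the mutant was located in the reference annotation. Wdhd1 (ENSMUSG00000037572) is a protein-coding gene on the minus strand of chromosome 14, from 47240944 to 47276857 in mm10, with 6 annotated transcripts. In Wdhd1-204, which encodes 1118 residues over 25 exons, the residue at the position named in the label is a threonine followed by glutamine, within the peptide ELAETQSEE. Its codon, ACC, lies in the coding part of exon 18, at 47248046 to 47248048. The transcript reads GAATTGGCAGAAACCCAGTCAGAAGAA around it, from 47248060 down to 47248034. A threonine before a glutamine is the minimal target motif of the checkpoint kinases ATR and ATM. In the shorter coding transcript Wdhd1-202, with 1081 residues, the residue of the same number lies at a different site. It is an alanine with the codon GCT, in exon 19 at 47247838 to 47247840, within the peptide QVEDAEDRE. The label's numbering therefore matches Wdhd1-204 and not Wdhd1-202. The genotype itself was not checked here.

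The AND-1 T819A libraries held fewer cell barcodes than the wild-type libraries in both sexes, but 2 libraries per genotype are too few to separate this from chance. The wild-type libraries held 20937 barcodes in the female and 18592 in the male. The AND-1 T819A libraries held 17288 in the female and 18194 in the male. The mean was 19764.5 ± 1658 (SD, n = 2) for wild type and 17741 ± 641 (SD, n = 2) for AND-1 T819A. The mean difference of AND-1 T819A minus wild type was -2023.5 barcodes, or a ratio of 0.898. An exact two-sided permutation test gave p = 0.333, which is the smallest value that the 6 assignments of 4 libraries allow. It exchanged genotypes across the sexes, and so ignored that each sex held 1 library per genotype. Within the female mice the ratio of AND-1 T819A to wild type was 0.826 (95% exact interval 0.809 to 0.843). Within the male mice it was 0.979 (0.959 to 0.999). These intervals cover counting error only, and each rests on 1 library per genotype, so neither ratio has a replicate check. The 2 wild-type libraries differed by 2345 barcodes, more than the mean difference between genotypes, but this gap also holds any difference between the sexes. The differences between genotypes within each sex had an SD of 2299 barcodes (n = 2). Without the female wild-type library the mean difference was -851 barcodes, and without the male wild-type library it was -3196. The male libraries carry their sex under a label named batch, so sex and any batch cannot be told apart.

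**Figure D1:**
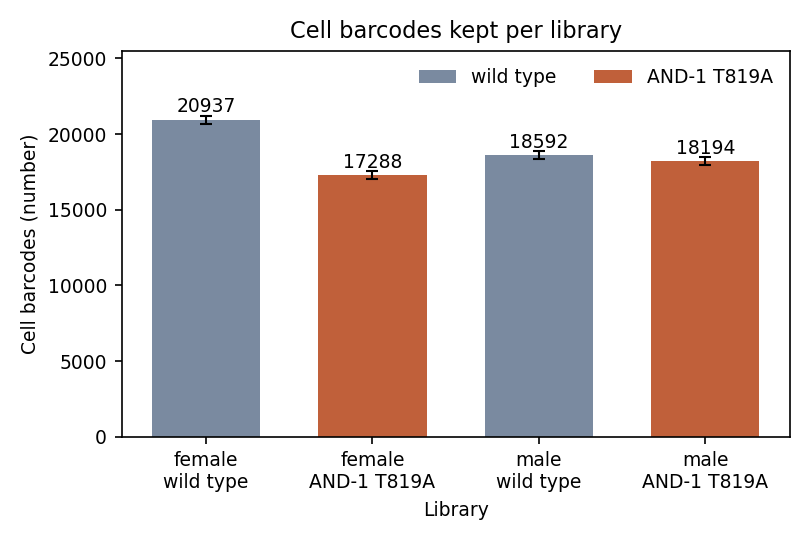
Number of barcodes called as cells (y axis) in each of the 4 libraries (x axis), coloured by genotype, with 95% exact Poisson intervals that cover counting error only. The female AND-1 T819A library is the smallest at 17288 and the female wild-type library the largest at 20937, while the male libraries differ by 398.

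The genes against which reads were counted were the same in all 4 libraries. Each list named 32285 gene IDs under 32245 distinct symbols, in the same order. Of the IDs, 32235 (99.8%) were found in GENCODE M21, an annotation of the same assembly. The lists held 21702 of the 22028 protein-coding genes of that annotation (98.5%) and all 494 immunoglobulin and T cell receptor gene segments. They held 8560 of 8813 lincRNA and antisense genes (97.1%). By contrast, 6 of 13317 pseudogenes outside the immune receptor loci were listed (0.0451%), and 0 of 6039 small and ribosomal RNA genes. The 13 protein-coding genes of the mitochondrial genome were listed. RNA of the omitted classes therefore had no gene of its own to be assigned to.

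All genes chosen beforehand for the expression comparison were in the lists of genes counted. These were 171 genes in 7 pathway lists and 22 sets of cell type markers, and 2 of them appeared under another symbol. H2ax, the histone variant phosphorylated at DNA breaks, was listed as H2afx. Sting1, the adaptor of cytosolic DNA sensing, was listed as Tmem173. The list of replication fork proteins and AND-1 partners had all 24 members, among them Mcm2 to Mcm7 of the replicative helicase, Cdc45, Pola1 and Timeless. The list for replication stress and the DNA damage response had all 16 members, including Atr, Chek1 and Rrm2. The 12 p53 targets, the 11 interferon and cytosolic DNA sensing genes, the 8 Wnt and stem cell genes, the 7 apoptosis genes and the 9 inflammation genes were likewise complete. No gene of these lists shared its symbol with another ID. Neurod1, an enteroendocrine transcription factor, shared 7.37% of its exon bases with Cerkl on the same strand. The stem cell marker Olfm4 shared 5.17% with Gm6999. Wdhd1 shared no exon bases with another listed gene on its own strand. On the opposite strand, 4.68% of its exon bases overlapped Gm49150, an antisense gene at 47276370 to 47276796, at the 5′ end of Wdhd1.

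The barcode lists were compared to find libraries that overlapped. No pair of libraries held the same cells, since at most 0.586% of the barcodes of the smaller library occurred in the other. Over the 6 pairs, 570 shared barcodes were found (95% exact Poisson interval 524 to 619). Independent draws from the v3 barcode list, the list used with the kit named in the labels, would give 310.0, so the observed number was 1.84 times the expected one (1.69 to 2.00). The interval lay above the expected number in all 6 pairs. The smallest ratio, 1.69 (1.33 to 2.10), was that of the female and male AND-1 T819A libraries, with 78 shared barcodes. The largest, 1.97 (1.59 to 2.41), was that of the female AND-1 T819A and male wild-type libraries, with 93. In total 555 barcodes occurred in exactly 2 libraries, 5 in 3 libraries and 0 in all 4. The excess depends on the size taken for the list. The combinations that the barcode parts allow, a size chosen after seeing the data, are 54.1% of the number in the v3 list. With that size 573 shared barcodes were expected over all pairs, a ratio of 0.994 (0.914 to 1.08).

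**Figure D2:**
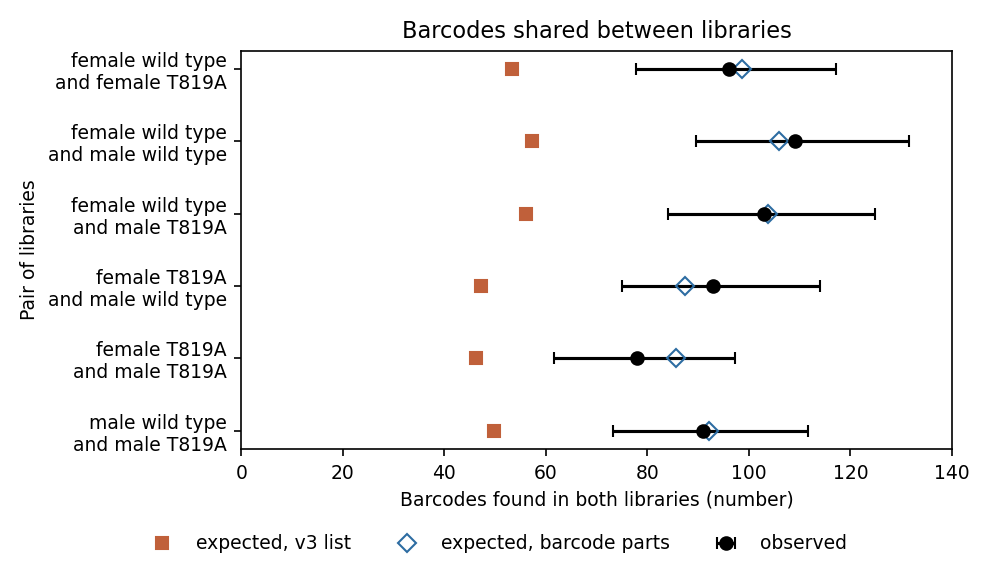
Number of barcodes found in both libraries of a pair (x axis) for the 6 pairs of libraries (y axis). Black points are the observed numbers with 95% exact Poisson intervals, squares the numbers expected from the v3 list, and diamonds those expected from the combinations that the barcode parts allow. Every square lies below its interval and every diamond lies within it.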

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

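The difference in barcodes between genotypes stayed negative in every alternative run, and the exact permutation test cannot go below 0.333 wherever it can be run. Each AND-1 T819A library held fewer barcodes than either wild-type library, so leaving out a library or comparing within a sex could not reverse the sign. Leaving out each library in turn gave -3196 to -851 barcodes, against -2023.5 with all. Without the female wild-type library it was -851, and without the male wild-type library -3196. The difference was -3649 within the female mice and -398 within the male mice, so the female pair carries most of it. Dropping barcodes found in another library gave a difference of -1991. It left 20631, 17025, 18303 and 17927 barcodes in the female wild-type, female AND-1 T819A, male wild-type and male AND-1 T819A libraries. Each number lay below its counting interval, but dropping barcodes can only lower a number. Merging barcodes 1 base apart moved nothing, because 0 such pairs exist. The excess of shared barcodes ended with the size of the barcode list. With the size given by the barcode parts, chosen after seeing the data, the ratio over all pairs was 0.994, and the change follows from the smaller list alone. By pair, this size and the size estimated from the other pairs gave 0.974 and 0.976 for the female libraries, and 0.988 and 0.993 for the male libraries. They gave 0.993 and 0.999 for female wild type with male AND-1 T819A, and 0.911 and 0.903 for the AND-1 T819A libraries. In the 2 pairs left the ratio stayed above 1 without its interval excluding 1. The size estimated from the other pairs only compares pairs with each other. An excess common to all pairs would not show in it. The lists of genes were the same by ID (32285) and by symbol (32245). The alternatives listed beforehand for expression, cell classes and gene lists were not run, as no counts were analysed.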

Other observations

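All tests in this part were chosen after the sharing of barcodes had been seen, and no biological explanation was tested. The barcodes of the 4 libraries have a regular structure. Over the 74446 distinct barcodes, bases 1 to 7 took 3840 values and bases 10 to 16 took 3826. Each of these was tied to 1 of 4 linking pairs of bases at positions 8 and 9 (AG, CA, GT or TC), in 100% of cases. Each link had 960 first parts and 947 to 960 last parts, and 24.6% to 25.5% of the barcodes. Each first part was seen in at least 3 barcodes and each last part in at least 6, so few parts can have been missed. No 2 barcodes of the whole set were 1 base apart, where 31.0 such pairs would occur among random sequences of this length.

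The parts allow 3672960 combinations, which is 54.1% of the number in the v3 list. The sharing between libraries, which does not use the parts, gave a list of 3695380 barcodes (95% interval 3404095 to 4018551). With the combinations as the list, 573 shared barcodes were expected and 570 seen, a ratio of 0.994 (0.914 to 1.08). This ratio restates the comparison of the list sizes and is not separate support. By pair, the interval held 1 in all 6 pairs. These values are consistent with barcodes drawn from a list smaller than that of the v3.1 kit named in the labels. A candidate explanation is that another kit generation was used than the label says, and the identity of the list was not tested, since no barcode list was used here. The size of the list does not test whether barcodes were carried from one library into another, since carried barcodes would come from the same list. With the combinations as the list, independent draws alone give about the number seen. A small number of carried barcodes stays open, as the upper end of the interval exceeds the expected number by 45.3. The ratio was 0.981 (0.845 to 1.13) for the 2 pairs of the same sex and 1.00 (0.903 to 1.11) for the 4 pairs of different sex. One library deposited under a pair of names is excluded by the highest overlap of 0.586%.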
